A study of Mus musculus with 6 samples.

How the data were processed

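RNA was measured in 6 mouse libraries, 3 from sorted leukaemia stem and progenitor cells of untreated mice and 3 from those of tamoxifen-treated mice, grouped by the sample titles. Per the labels' protocols, total RNA was extracted with Qiagen columns and libraries were made with a standard Illumina protocol. The deposited files, 1 per library, hold whole-number counts per gene symbol as the authors made them, with no normalization. Per the submitters' processing notes, FastQC, TopHat2 2.1.0, featureCounts and DESeq2 were used with the mouse build mm9, without a role or order being given. The gene annotation, the strand setting, the treatment of reads that map to several places, and the sort gates are not given in the sources used here. If reads were counted without strand, a gene and its antisense partner share counts, and if reads with several positions were dropped or split, genes with near-identical copies are counted too low or unevenly. The files list no mitochondrially encoded gene, so the share of such counts was not analysed here.

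From the counts, library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.986 to 1.007. Genes were kept by filterByExpr with a minimum of 10 counts, which left 12729 of 24015. The groups were compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest) with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled, and means are given with the SD over 3 libraries. Where a group had no count for a gene, the fold is a lower bound against a floor of 3 counts over that group; where it had 1 to 3 counts, the ratio is given with its exact 95% interval, which covers counting error only.

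Before the data were examined, 38 gene lists were fixed from textbook pathways and cell type markers. Those with at least 5 tested members, 33 lists, were tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way and compares them with no other genes, were run beside it. With an estimated correlation, camera has only the residual degrees of freedom of 6 libraries, and therefore little power. For each list, members that passed over all genes tested and members that passed when p was adjusted over the list alone were counted.

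Named genes were chosen by a rule fixed at the same time. It takes a panel of 12 genes (Map3k14, Nfkb2, Relb, Nfkb1, Rela, Traf3, Dnmt3a, Mef2c, Hoxa9, Meis1, Myc and Cdkn1a), of which Dnmt3a and Mef2c came from knowledge of the study. It adds the 10 genes that rose and the 10 that fell with the largest fitted log2 fold changes among those that passed, had an average log2 CPM of at least 1 and did not overlap between groups. For each list that passed, or had at least 3 members that did, it adds the up to 4 passing members with the smallest p. All other genes named, among them those that make up a count of 5 or fewer, were chosen after their values were seen. A gene that the rule takes and a cell type marker are not reported here; the counts of named genes and of list members include them where they were tested.

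The alternatives fixed beforehand were RLE, upper quartile and no scaling factors, no filter and a stricter filter (CPM above 1 in at least 3 libraries), DESeq2 1.42.0, limma voom, the replicate number as a block, a required change of more than 1.5-fold (glmTreat), leaving out each library in turn and the other set tests. The same fit was run on all 10 splits of the 6 libraries into 3 and 3.

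For neighbouring genes, symbols were matched to the RefSeq genes of GRCm38, which is not the build of the counts, so only the order of genes was used and no coordinate is given; 94.4% of tested genes matched. Pairs of adjacent tested genes that both rose were counted and compared with 10000 permutations of the calls among genes of like expression. Tests with cell type markers compare CPM sums between libraries. A scan of 392 groups of genes with a shared symbol stem was added after the data were seen.

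The test was tried on simulated counts with the means, dispersions and library sizes of these 6 libraries, 12729 genes, of which 200 were changed. It recovered 22.6% of the genes changed 1.5-fold, 65.2% of those changed 2-fold and 84.1% of those changed 4-fold, and it called 10 unchanged genes. Changes under 2-fold were thus often missed in the simulation. In the data 2189 genes passed, and the adjustment is less strict for each gene where more genes change. The shares recovered therefore hold for the simulation and may be too low for the data. With no change simulated it called 1 gene and no list. The simulated genes varied independently of each other, so this does not show how often lists are called falsely where genes vary together. Depth ran from 19999071 to 26773176 counts per library.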

Results

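Gene expression was measured by RNA sequencing in 6 libraries of leukaemia stem and progenitor cells, sorted from mice with fully developed acute myeloid leukaemia driven by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9. The leukaemia had been started from lineage-negative, Kit-positive bone marrow progenitors that carried a silenced transgene for the kinase NIK (gene Map3k14) and a tamoxifen-dependent Cre recombinase, which removes the stop in front of the transgene. Of the 6 libraries, 3 came from untreated mice and 3 from mice given tamoxifen. The comparison of the groups asks what switching on NIK does to gene expression in the leukaemia cells. Tamoxifen was given only to the mice in which NIK was switched on, so the effects of the drug, of Cre and of NIK cannot be separated in these samples.

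Total counts were 20410001, 23639689 and 26773176 in untreated replicates 1 to 3 and 19999071, 21541142 and 22454753 in tamoxifen replicates 1 to 3. At this depth, 3 counts, the limit that a count of 0 allows, correspond to 0.112 to 0.150 CPM per library, for counting error only. Of 24015 genes listed, 6156 had no count in any library and 12729 were tested. Libraries of the same group had Spearman correlations across genes of 0.977 to 0.994, against 0.956 to 0.966 between groups, where genes are not independent replicates. No library pair differed by so little that it could be 1 library under both names (chi-square per degree of freedom of 11.5 to 50.7 within groups). The first principal component, 62.6% of the variance, separated the groups, and the second, 17.2%, placed tamoxifen replicate 1 at 48.2, apart from tamoxifen replicates 2 and 3 at -25.8 and -18.6. Nothing in the labels says that the replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

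Map3k14 itself was higher in every tamoxifen library. Its level was 26.5, 24.2 and 28.8 CPM in the untreated libraries and 129.9, 190.6 and 159.5 CPM in the tamoxifen libraries, a log2 fold change of 2.59 with a standard error (SE) of 0.15 (edgeR quasi-likelihood adjusted p = 4.35e-05). Counts do not tell transcripts of the transgene from those of the endogenous gene. The DNA methyltransferase gene Dnmt3a rose from 109.9 ± 6.26 to 380.0 ± 68.2 CPM (SD, n = 3; log2 1.79, SE 0.14, edgeR adjusted p = 0.000141). Mef2c, a transcription factor gene of MLL-rearranged leukaemia, fell from 171 ± 19.2 to 34.8 ± 7.25 CPM (SD, n = 3; log2 -2.29, SE 0.17, edgeR adjusted p = 0.000124). Dnmt3a and Mef2c were picked for the panel from knowledge of the study, so their direction is not independent evidence. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.51 on the log2 scale (SE 0.21, edgeR adjusted p = 0.00274). Among the other panel genes, Meis1 (log2 -0.10, edgeR adjusted p = 0.640) and Myc (log2 0.16, edgeR adjusted p = 0.372) did not pass. Hoxa9 stood at 430 CPM in tamoxifen replicate 1 and at 159 and 154 CPM in replicates 2 and 3, against 215 to 269 CPM untreated. Its log2 difference of -0.02 did not pass (edgeR adjusted p = 0.983), and without tamoxifen replicate 1 it was -0.67 (edgeR adjusted p = 0.00398).

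**Figure D1:**
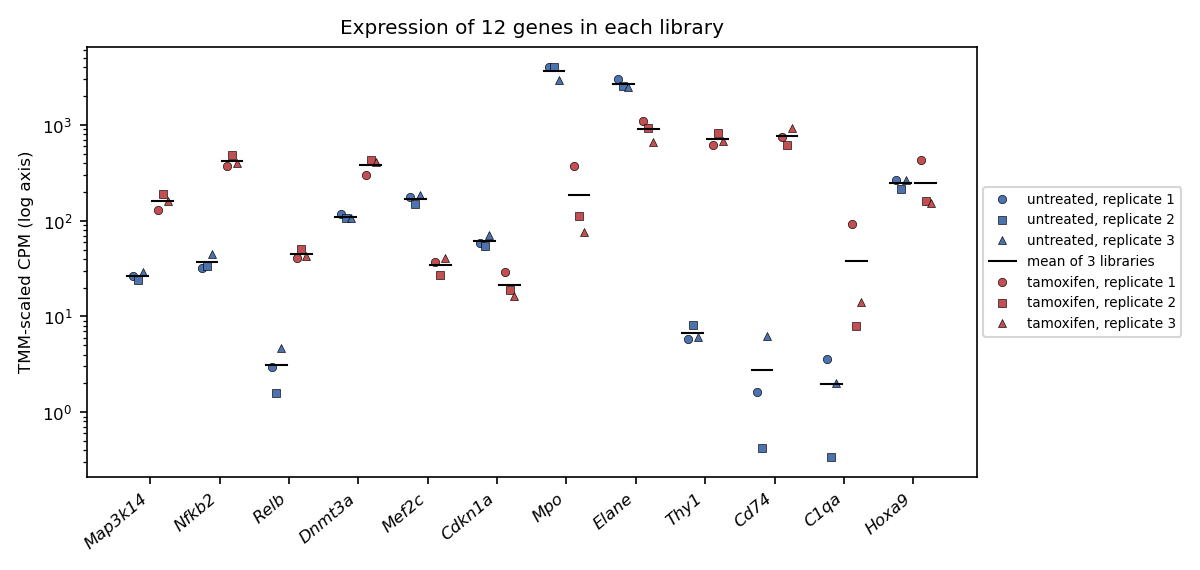
Expression of 12 genes in each of the 6 libraries, in TMM-scaled CPM on a log axis. Points are single libraries, with a marker shape for the replicate number and a colour for the group, and black lines are means of 3 libraries. Map3k14 lay between 24.2 and 28.8 CPM in the untreated and between 129.9 and 190.6 CPM in the tamoxifen libraries, and C1qa and Hoxa9 stood higher in tamoxifen replicate 1 than in replicates 2 and 3.

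In all, 1140 genes rose and 1049 fell with tamoxifen (2189 of 12729 tested, 17.2%; edgeR quasi-likelihood test, adjusted p under 0.05, two-sided). At least 2-fold changes made up 667 of the genes that rose and 331 of those that fell. The groups did not overlap for 4795 tested genes (37.7%, against 10% by chance for 3 against 3). The largest rises were in genes close to silent in the untreated libraries. Ackr1, an atypical chemokine receptor gene, had no count in the untreated libraries and was at least 456-fold higher, Gstt1, a glutathione transferase gene, at least 224-fold and Aoc1, an amine oxidase gene, at least 110-fold, each against a floor of 3 counts over the group. Cadm3, a cell adhesion gene that overlaps Ackr1 in RefSeq, rose from 0.0614 ± 0.0537 to 139 ± 35.5 CPM (SD, n = 3). As the strand setting is not given, the counts of either gene may include reads of the other. Dlk1, a non-canonical Notch ligand gene, rose from 0.715 ± 0.109 to 189.9 ± 70.2 CPM, and Cd74, the invariant chain of MHC class II, from 2.77 ± 3.07 to 770.3 ± 161 CPM (SD, n = 3). Ccdc184 (log2 9.47), Trim29 (8.38) and the sialyltransferase gene St6galnac1 (7.73) completed the list of 10 with 5730460C07Rik, which had 1 count in the untreated libraries and 256 in the tamoxifen libraries (ratio 282, 95% counting interval 50.2 to 11179).

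The largest falls included Mpo, the myeloperoxidase of neutrophil primary granules, which went from 3683 ± 643 to 187 ± 162 CPM (SD, n = 3; log2 -4.30, SE 0.58, edgeR adjusted p = 0.00213). Prr19 had no count in the tamoxifen libraries and was at least 86.9-fold lower. Col19a1, a collagen gene, fell by 5.53 on the log2 scale and Nt5e, the gene of the ecto-nucleotidase CD73, by 3.69. Ccm2l (log2 -3.70), Fam174b (-3.56), Kcng2 (-3.55), the thyrotropin receptor gene Tshr (-3.26) and Stxbp6 (-3.25) also fell. Hebp2 (log2 -3.29, edgeR adjusted p = 0.0454) rested on 4.16 CPM in the untreated libraries and missed the threshold when any library other than tamoxifen replicate 1 was left out (adjusted p 0.0825 to 0.137), and passed without that replicate (adjusted p = 6.77e-05), where the other tamoxifen libraries held 1 count each, too few for a plain fold. Without tamoxifen replicate 1, 3249 genes passed, and without untreated replicate 1, 1029 did. Leaving out untreated replicate 2, 1242 passed, and with a required change of more than 1.5-fold, 647.

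Genes of the noncanonical NF-kB pathway, in which NIK activates the processing of p100 to p52, were higher with tamoxifen. Of 12 tested members, 6 rose and none fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0194; adjusted p = 0.537 with an estimated correlation, which did not pass). Nfkb2, which encodes p100, rose from 37.0 ± 7.09 to 423 ± 56.4 CPM and its partner Relb from 3.07 ± 1.58 to 44.7 ± 5.67 CPM (SD, n = 3). The ubiquitin ligase genes Birc3 (log2 2.02, SE 0.14) and Birc2 (0.78, SE 0.10) rose, as did Traf2 (0.50) and the receptor gene Cd40 (4.03), which had counts in untreated replicate 3 alone of the untreated libraries (0.223 CPM), so that no plain fold can be given without it. Traf3, whose product targets NIK for degradation, differed by 0.43 (edgeR adjusted p = 0.0846), which passed without tamoxifen replicate 1 (adjusted p = 0.00133) and with DESeq2 (0.0216). Map3k14 was left off this list because it was the gene switched on.

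NF-kB response genes rose as a list as well, with 16 of 35 tested members higher and 2 lower, the same numbers adjusted over the list alone (camera adjusted p = 3.15e-05; adjusted p = 0.537 with an estimated correlation). The list also holds Nfkb2, Relb, Birc3 and Cd40, 4 of the 6 genes that rose in the noncanonical list, so the calls of these lists rest partly on the same genes. Its feedback inhibitors were among the clearest: Tnfaip3, which encodes A20, rose from 19.5 ± 2.31 to 148 ± 17.0 CPM, Nfkbia from 86.5 ± 11.1 to 365 ± 9.66 CPM and Nfkbie from 15.5 ± 1.81 to 74.6 ± 6.54 CPM (SD, n = 3). The 2 members that fell were Plaur (log2 -1.70) and Csf1 (-1.60), named after their values were seen. The canonical NF-kB genes did not move as a list (4 of 20 rose and 2 fell, also adjusted over the list alone; camera adjusted p = 0.862). Tlr2 (log2 1.33), Tlr4 (0.82), Il1r1 (0.82) and Cyld (0.59) rose, whereas Ripk1 (-0.47) and Tnfrsf1a (-0.46) fell. Nfkb1 (log2 0.15, edgeR adjusted p = 0.275) and Rela (-0.06, 0.674) did not pass. Of the 10 lymphoid targets of p52 and RelB, only 4 were expressed enough to be tested and no set test was made; among these Ltb (log2 4.999) and Vcam1 (2.98) rose, and no member fell, with the same count adjusted over the list alone.

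Interferon-stimulated genes were the list with the smallest p. Of 40 tested members 29 rose and 1 fell (32 and 1 adjusted over the list alone; camera adjusted p = 6.16e-16; adjusted p = 0.203 with an estimated correlation), with a median log2 fold change of 1.44. Ddx58, the gene of the RNA sensor RIG-I, rose from 12.996 ± 2.72 to 54.8 ± 3.47 CPM (SD, n = 3). The antiviral genes Oasl1 (log2 3.14), Oasl2 (3.61) and Ifi27l2a (3.77) rose. Gbp3 was the member that fell (-0.88), named after its value was seen. Oas, Gbp and Ifi genes have close copies whose reads could have been split in counting.

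Antigen presentation genes rose too, with 12 of 21 members higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 1.85e-05; adjusted p = 0.249 with an estimated correlation). Among the MHC class II genes and their activator, H2-Aa went from 1.23 ± 1.06 to 249.6 ± 67.6 CPM, H2-Eb1 from 1.38 ± 0.962 to 210.2 ± 67.9 CPM, H2-Ab1 from 21.5 ± 2.46 to 269.9 ± 58.1 CPM and the activator Ciita from 0.208 ± 0.239 to 26.4 ± 7.51 CPM (SD, n = 3). Tap2, a peptide transporter gene, was the member that fell (log2 -0.66), named after its value was seen. Cd74 and these 4 genes did not stand apart in tamoxifen replicate 1, with a median log2 difference of -0.03 between it and the mean of replicates 2 and 3. Each was highest in replicate 3 and lowest in replicate 2 (Cd74 at 937.6 and 616.3 CPM).

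**Figure D2:**
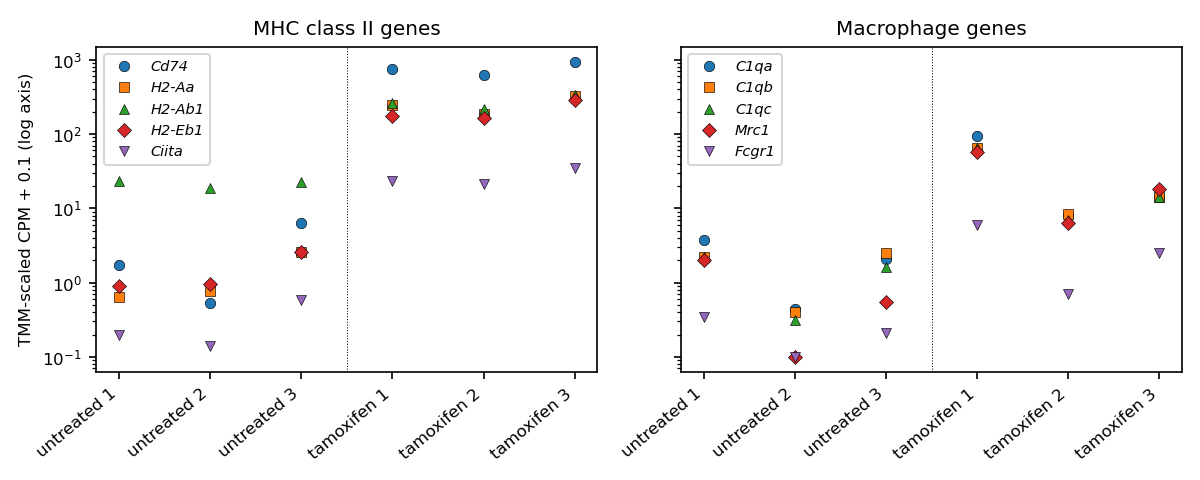
TMM-scaled CPM, plus 0.1, on a log axis in each library for 5 MHC class II genes (left) and 5 macrophage genes (right), with a dotted line between the groups and 1 marker per gene. Cd74 lay between 616 and 938 CPM in the tamoxifen libraries, whereas C1qa was at 92.6 CPM in tamoxifen replicate 1 and at 8.03 and 14.3 CPM in replicates 2 and 3.

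Primary granule genes, and other genes of granulocyte-monocyte progenitors on the same list such as Hdc and Gstm1, fell as a list. None of 12 rose and 7 fell (9 adjusted over the list alone; camera adjusted p = 0.000169; adjusted p = 0.537 with an estimated correlation). Besides Mpo, the neutrophil elastase gene Elane fell from 2696 ± 296 to 899.8 ± 226 CPM, the histidine decarboxylase gene Hdc from 43.6 ± 5.58 to 4.88 ± 1.996 CPM and Gstm1 from 559.9 ± 61.6 to 230.4 ± 64.6 CPM (SD, n = 3). Neutrophil maturation genes did not move as a list (2 of 26 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.778): Pglyrp1 (log2 1.68) and Ncf1 (0.47) rose and Hp (-0.45) fell.

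Monocyte and macrophage genes went both ways, with 7 of 32 higher and 8 lower (11 and 10 adjusted over the list alone; camera adjusted p = 0.810). The monocyte transcription factor gene Irf8 (log2 -1.14), Mpeg1 (-1.29) and the Fc receptor gene Fcgr3 (-0.49) fell, and Emr1, which encodes the macrophage marker F4/80, rose (1.005). The macrophage genes C1qa, C1qb, C1qc, Mrc1 and Fcgr1, named after their values were seen, rose by 4.17 to 5.18 on the log2 scale. They stood higher in tamoxifen replicate 1 than in the mean of replicates 2 and 3 by a median log2 difference of 2.59, and without that replicate they rose by 2.51 to 4.03 (edgeR adjusted p 0.0116 to 0.0268). All 5 genes missed the threshold with limma voom (adjusted p 0.0618 to 0.145, log2 3.98 to 6.17). In edgeR, C1qa, C1qb, C1qc and Fcgr1 missed it without untreated replicate 1 (adjusted p 0.0530 to 0.0691) or 2 (0.0525 to 0.0829), C1qa and Fcgr1 without untreated replicate 3 (0.0743 and 0.0624) and Fcgr1 without tamoxifen replicate 3 (0.0506).

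Genes of the MLL-AF9 programme split evenly, 6 of 32 rising and 6 falling, also adjusted over the list alone (camera adjusted p = 0.862). Besides Mef2c, the anti-apoptotic gene Bcl2 fell from 82.7 ± 11.8 to 25.2 ± 4.29 CPM and Pbx3, a Hoxa cofactor gene, from 25.8 ± 5.50 to 7.53 ± 1.24 CPM, whereas the chromatin organiser gene Satb1 rose from 12.03 ± 0.821 to 37.9 ± 8.44 CPM (SD, n = 3). Of 21 haematopoietic stem cell genes, 4 rose and none fell (5 and none adjusted over the list alone; camera adjusted p = 0.105). Thy1 rose from 6.73 ± 1.30 to 709 ± 109 CPM (SD, n = 3), Gata2 by 1.12, Mycn by 1.597 and the angiopoietin gene Angpt1 by 0.70 on the log2 scale. The stem cell list passed with fry, which does not compare it with other genes (adjusted p = 0.00674).

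Mitosis genes were slightly higher as a list (6 of 36 rose and none fell, 7 and none adjusted over the list alone; median log2 0.20; camera adjusted p = 0.000339). This call was lost with an estimated correlation (adjusted p = 0.817 with an estimated correlation) and with fry (adjusted p = 0.133). Nusap1 (0.84), the spindle checkpoint gene Bub1b (0.62), Ndc80 (0.44) and Birc5 (0.43) rose. DNA replication genes did not move as a list (1 of 36 rose and 5 fell, also adjusted over the list alone; camera adjusted p = 0.376): the thymidine kinase gene Tk1 rose (0.79), and Ccne2 (-0.86), the licensing gene Cdc6 (-0.54), Mcm2 (-0.35), Cdt1 (-0.33) and Cdc45 (-0.27) fell. Among 12 CDK inhibitors and related genes Cdkn1a alone passed, also adjusted over the list alone (camera adjusted p = 0.839). For MYC and ribosome biogenesis genes, none of 36 rose and 4 fell (3 adjusted over the list alone; camera adjusted p = 0.156), namely Cad (-0.61), Srm (-0.42), Polr1a (-0.35) and Nop2 (-0.32); this list passed as lower without untreated replicate 3 (adjusted p = 0.0250).

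The p53 targets went both ways, 3 of 31 rising and 3 falling, also adjusted over the list alone (camera adjusted p = 0.839): the death receptor gene Fas (2.28), the DNA repair gene Xpc (0.63) and Trp53inp1 (0.68) rose, and Cdkn1a, Sesn2 (-1.32) and Aen (-0.33) fell. Of 37 BCL2 family and death receptor genes 8 rose and 7 fell (10 and 10 adjusted over the list alone; camera adjusted p = 0.908). Fas and Birc3 rose, and Bcl2 and the pro-apoptotic gene Bid (log2 -0.98, SE 0.10) fell. In the DNA methylation list of 18, Dnmt3a rose and Dnmt3l (-1.32) and Idh2 (-0.43) fell (1 each way adjusted over the list alone; camera adjusted p = 0.191); Idh2 passed only just (edgeR adjusted p = 0.0491) and missed the threshold with RLE factors, upper quartile factors and the stricter filter (0.0547, 0.0763 and 0.0621). Polycomb and trithorax genes gave 2 of 31 that rose, Cbx7 (1.73) and Jarid2 (0.45), and 3 that fell, Cbx8 (-1.08), Kdm2b (-0.62) and Rnf2 (-0.57), with 2 and 5 adjusted over the list alone (camera adjusted p = 0.134).

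Among metabolic genes, 7 of 28 cholesterol and lipid synthesis genes rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.112; fry adjusted p = 0.0199). Cyp51 (0.48) rose, and the fatty acid synthesis genes Fasn (-0.56), Acaca (-0.51) and Scd2 (-1.06) fell. Glycolysis and hypoxia genes went both ways (4 of 28 rose and 4 fell, 9 and 5 adjusted over the list alone; camera adjusted p = 0.502): Aldoc (2.30), Hif1a (0.88), Pfkm (0.82) and Eno1 (0.38) rose, and Egln1 (-0.71), Egln3 (-0.66), Hk2 (-0.60) and Slc2a3 (-1.16) fell. Of 39 oxidative phosphorylation genes, Cyc1 alone passed (-0.31), and none did adjusted over the list alone, where 4 were lower at an unadjusted p under 0.05 (edgeR; camera adjusted p = 0.519). In the unfolded protein and ATF4 list of 28, the serine synthesis gene Phgdh rose (2.95) and Sesn2 fell, also adjusted over the list alone (camera adjusted p = 0.443). Adhesion and homing genes gave 4 of 24 that rose, Cd96 (3.73), Cd36 (3.06), the integrin gene Itgb3 (1.71) and Cd274 (1.46), and 3 that fell, Itgb7 (-2.07), Itga5 (-0.64) and Selplg (-0.39), with 5 and 5 adjusted over the list alone (camera adjusted p = 0.839). Of 13 oestrogen-responsive genes, included because tamoxifen binds oestrogen receptors, Ctsd rose (0.47) and Siah2 fell (-0.70), also adjusted over the list alone (camera adjusted p = 0.519).

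Markers of other blood and marrow cells were checked because a sort can hold such cells. T and NK cell markers were higher, with 7 of 16 rising and 1 falling (9 and 1 adjusted over the list alone; camera adjusted p = 0.000858; adjusted p = 0.768 with an estimated correlation). The chemokine gene Ccl5, which is also an NF-kB response gene, rose from 0.323 ± 0.203 to 10.3 ± 2.76 CPM, Lck from 12.98 ± 0.361 to 35.4 ± 17.5 CPM and Il7r from 3.26 ± 0.585 to 9.26 ± 3.50 CPM, whereas Nkg7 fell from 51.7 ± 4.53 to 12.6 ± 5.90 CPM (SD, n = 3). Dendritic cell markers (4 of 10 rose and 1 fell, 7 and 1 adjusted over the list alone; camera adjusted p = 0.0136) and mast cell and basophil markers (3 of 10 rose and none fell, also adjusted over the list alone; camera adjusted p = 0.0194) passed as lists, both with adjusted p = 0.537 with an estimated correlation. The dendritic genes Fscn1 (log2 2.53), Ccr9 (2.27), Ccr7 (2.002) and Ly6d (1.28) rose and Flt3 fell (-1.20). Gata2 rose, as did the eosinophil genes Prg3 (log2 3.58) and Ccr3 (6.14). Prg3 stood at 85.5, 16.7 and 30.6 CPM in tamoxifen replicates 1 to 3 and Ccr3 at 14.6, 2.14 and 2.88 CPM. Without replicate 1 they rose by 2.68 and 4.77. Prg2, also on this list, did not pass (log2 1.37, edgeR adjusted p = 0.403). It stood at 66.5, 4.36 and 3.32 CPM in tamoxifen replicates 1 to 3, and without replicate 1 it was lower (-1.31, edgeR adjusted p = 0.0248). Endothelial and stromal markers gave 4 of 12 that rose, Pdgfra (3.28), Sparc (2.14), Col1a2 (1.80) and Col1a1 (1.75), and Pecam1 fell (-1.09), with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0648; it passed with no filter, 0.0197, and without untreated replicate 2, 0.0483, or tamoxifen replicate 2, 0.00415). Of 7 B cell markers only the adaptor gene Blnk rose (3.71), also adjusted over the list alone (camera adjusted p = 0.519).

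For these marker lists tamoxifen replicate 1 stood above the mean of replicates 2 and 3 by a median log2 difference of 0.999 for T and NK markers, 0.80 for endothelial and stromal, 0.51 for mast cell and basophil and 0.36 for dendritic markers, against 0.16 for interferon-stimulated genes and -0.00 for NF-kB response genes. Without it, the T and NK list passed (adjusted p = 0.00528), the dendritic (adjusted p = 0.0670) and mast cell and basophil lists (0.308) did not pass, and the latter also failed without untreated replicate 1 (0.243) and with no filter on low counts (0.0946). The T and NK list did not pass with fry (adjusted p = 0.0979). Of 3 erythroid markers tested, Car2 rose (log2 3.94), and Car2 and 1 fall passed adjusted over the list alone, while Hba-a1 and Hbb-b1 were at 0 in all 6 libraries. None of 4 megakaryocyte and platelet markers tested passed in edgeR, also adjusted over the list alone, and none had an unadjusted p under 0.05.

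Signs of RNA quality and library make-up were compared as well. The ribosomal RNA precursor Rn45s took 0.431% to 0.605% of counts in the untreated and 0.611% to 0.870% in the tamoxifen libraries, without overlap. Cytosolic ribosomal protein genes were lower as a list although none of 42 passed alone, also adjusted over the list alone (edgeR, with 2 lower at an unadjusted p under 0.05; median log2 -0.10; camera adjusted p = 0.0329; adjusted p = 0.941 with an estimated correlation). Replication-dependent histone genes, whose transcripts have no poly(A) tail and are near-identical within a core histone class, were higher as a list (camera adjusted p = 0.0329, and adjusted p = 0.863 with an estimated correlation). Of 18 tested members 1 rose, the linker histone gene Hist1h1e (log2 1.43), and none adjusted over the list alone. The ribosomal protein list missed the threshold in 8 of 15 alternatives, among them upper quartile factors (0.0760) and the fit without tamoxifen replicate 2 (0.312). The histone list missed it in 9 of 15, among them limma voom (0.117) and the fit without tamoxifen replicate 1 (0.641). Of 20 immediate early genes 1 rose, Klf6 (0.88; camera adjusted p = 0.877), and of 14 heat shock genes 1 fell, Hspa4l (-0.46; camera adjusted p = 0.237), both also adjusted over the list alone. The heat shock list passed without tamoxifen replicate 1 (adjusted p = 0.00901). Xist was at 1252 to 2049 CPM in all 6 libraries and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty at 12 counts or fewer per library. Xist differed by 0.40 and did not pass over all genes (edgeR adjusted p = 0.0819) but did adjusted over the list alone, as its only tested member, and over all genes with DESeq2 (adjusted p = 0.0168) and without tamoxifen replicate 1 (0.00467).

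**Figure D3:**
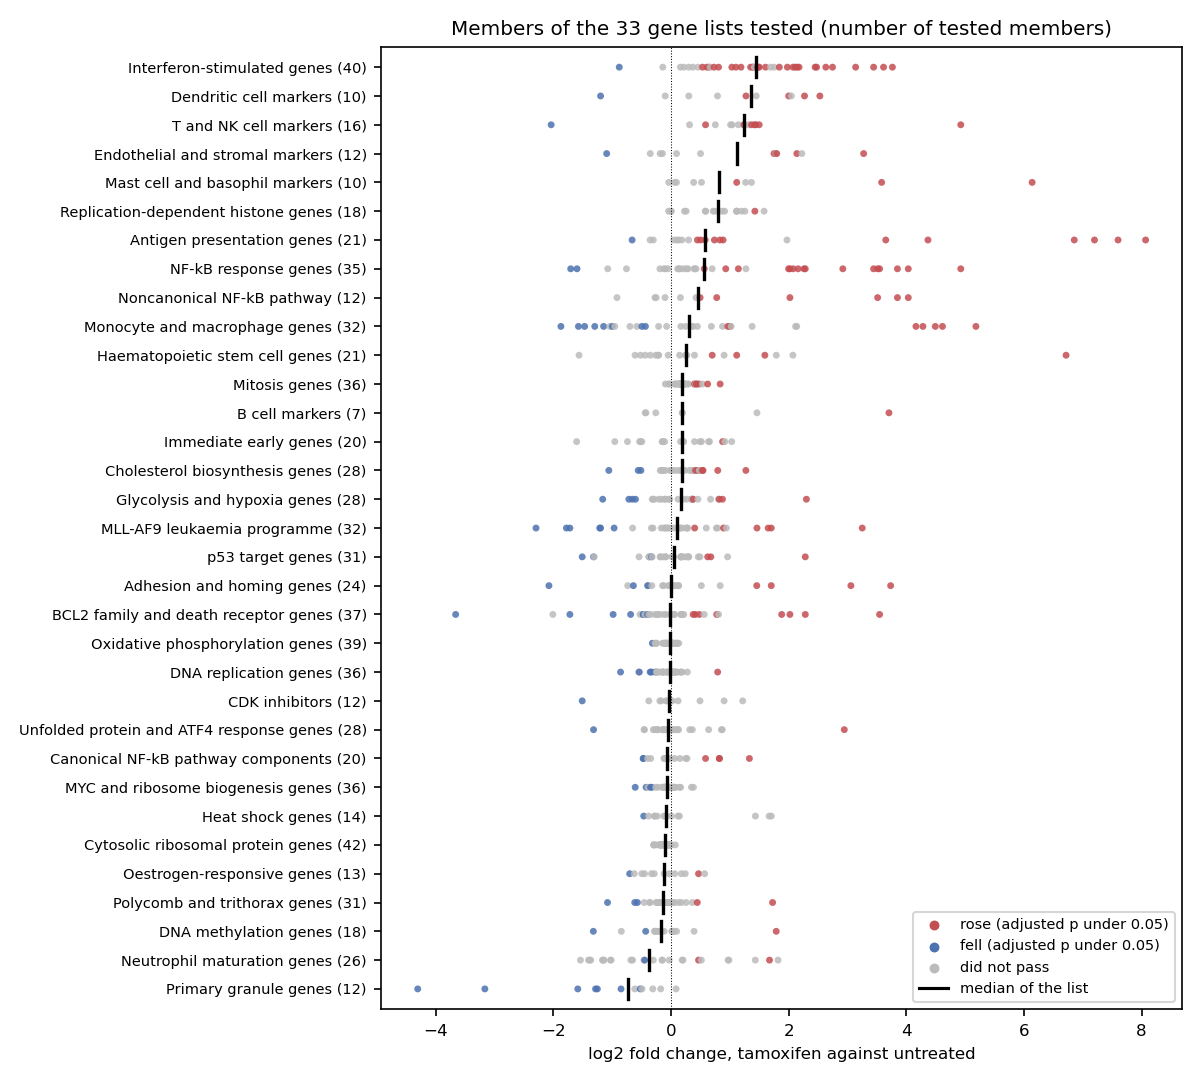
Log2 fold changes, tamoxifen against untreated, of the tested members of the 33 gene lists tested, 1 row per list in order of the median, with the number of members in brackets. Points are genes, coloured by whether they rose, fell or did not pass at an adjusted p under 0.05, and black bars are list medians. The median was 1.44 for interferon-stimulated genes at the top and -0.73 for primary granule genes at the bottom.

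Of the 33 lists tested, 9 rose and 2 fell by camera with a preset correlation of 0.01 between genes. None passed with an estimated correlation, where the smallest adjusted p was 0.203 and 2 lists had an unadjusted p under 0.05, and fry called 8 up and 1 down. With an estimated correlation camera has little power at 6 libraries, so it cannot decide whether correlation between genes made the calls. The stem cell list went from a camera adjusted p of 0.105 to 0.537 although its estimated correlation, -0.005, lay under the preset 0.01. Median, mean and test differed in sign for 9 of the 33 lists, none of which passed: the MLL-AF9 programme (median 0.10, mean 0.09, test down), p53 targets (0.05, 0.02, down), neutrophil maturation genes (-0.37, -0.22, up), canonical NF-kB genes (-0.06, 0.10, up), adhesion genes (-0.00, 0.28, up), CDK inhibitors (-0.04, 0.03, down), BCL2 family genes (-0.01, 0.02, down), unfolded protein genes (-0.05, 0.08, down) and heat shock genes (-0.08, 0.23, down).

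Several genes named by the rule overlap another listed gene in RefSeq, and as the strand setting of the counting is not given in the sources used here, their counts are uncertain to that extent. They are Nfkb2 with Psd, Dnmt3a with Dnmt3aos, Ackr1 and Cadm3 with each other, Cadm3 with Aim2, Ciita with Dexi, Ifi27l2a with Ifi27, Cbx7 with Apobec3, Dnmt3l with Aire, Tk1 with Afmid, Nusap1 with Oip5, Prg3 with P2rx3, Pfkm with Senp1, Acaca with Tada2a and Gm11437, Cad with Atraid, Ccne2 with Ints8, Ripk1 with Serpinb6a, and, with microRNA genes, Cd74 with Mir5107, Bcl2 with Mir3473f, Fcgr3 with Mir6546, Itga5 with Mir6963, Lck with Mir8119 and Pdgfra with Mir7025. Emr1 and Hist1h1e were not matched, and genes named outside the rule were not searched.

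Leaving out single libraries ended the call for 57 of the 162 named genes that passed, 54 of them without untreated replicate 1 (edgeR adjusted p 0.0520 to 0.192). These 54 were Hebp2, Cyld, Tnfrsf1a, Mycn, Ncf1, Pglyrp1, Mcm2, Bub1b, Birc5, Ndc80, Srm, Polr1a, Nop2, Idh2, Fasn, Cyp51, Itga5, Il7r, Lck, Ly6d, Pdgfra, Hist1h1e, Cd40, Tlr4, Il1r1, C1qa, C1qb, C1qc, Fcgr1, Cdt1, Cdc45, Trp53inp1, Aen, Jarid2, Scd2, Eno1, Egln3, Cyc1, Cd36, Cd274, Selplg, Ctsd, Siah2, Ccr7, Col1a1, Blnk, Klf6, Hspa4l, St6galnac3, Tlr3, Il4ra, Gstm5, Siglec1 and Itgad. Without untreated replicate 2 the calls of Il21r and Tlr1 were lost as well, and without tamoxifen replicate 3 that of Slc2a3. With limma voom 11 named genes missed the threshold: C1qa, C1qb, C1qc, Mrc1, Fcgr1, Hist1h1e, Egln3, Ccr7, St6galnac3, Siglec1 and Itgad. Upper quartile factors ended 9 calls (Hebp2, Nop2, Idh2, Cdt1, Cdc45, Aen, Egln3, Cyc1 and Gstm5), the stricter filter 6 (Idh2, Cdc45, Aen, Egln3, Cyc1 and Gstm5), no filter 4 (Cdc45, Aen, Eno1 and Cyc1) and RLE factors 2 (Idh2 and Aen).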

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

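All alternatives were chosen before the data were examined. Of 162 named genes that passed, 80 kept their direction and their call in every alternative run on them, 82 lost the call in at least 1, 74 of them when a change above 1.5-fold was required, and none reversed; Blnk, Cd36, Cd40, Cygb, Fcgr1, Pdgfra, Tlr3 and the B cell list were not tested under the stricter filter. Counts of genes stayed within 1.5 times of 2189 under other scaling factors, other filters, DESeq2 (2761) and limma voom (2163). With a change above 1.5-fold required, 647 genes passed, 420 up and 227 down, because that test asks for a larger change. Leaving out each library in turn gave 1029 to 3249 genes, 586 to 1657 up and 443 to 1592 down, lowest without untreated replicate 1 and highest without tamoxifen replicate 1; of the 2189 genes, 1018 and 2076 passed again. Fewer libraries lower the counts, but why the count rose without tamoxifen replicate 1 was not tested.

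With an estimated correlation 0 lists passed, 0 up and 0 down, in place of 11, 9 and 2. That version has few degrees of freedom here, so this loss does not show that correlation between genes made the calls. The number that fell was 1 with upper quartile factors, the stricter filter and fry, and ran from 1 to 3 when libraries were left out; the cause was not tested. Of the 11 lists, the noncanonical NF-kB, NF-kB response, primary granule, antigen presentation and interferon lists kept their call in all alternatives run on lists but the estimated correlation. DESeq2 and the required change of more than 1.5-fold were not run on lists.

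Directions turned only among results that did not pass. Hoxa9 was 0.028 with upper quartile factors, 0.0052 with the stricter filter, and -0.67 to 0.25 when libraries were left out. List directions turned for p53 targets with fry (adjusted p 0.127), BCL2 family genes with the stricter filter (0.853) and fry (0.183), and immediate early genes with upper quartile factors (0.972). When libraries were left out they turned for canonical NF-kB (0.572 to 0.913), the MLL-AF9 programme (0.352 to 0.989), neutrophil maturation (0.0598 to 0.973), monocyte and macrophage (0.156 to 0.913), CDK inhibitors (0.603 to 0.988), glycolysis (0.163 to 0.905), adhesion (0.135 to 0.960) and immediate early genes (0.0521 to 0.913). The cause was not tested.

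No pairing of the samples by replicate number was seen, though 3 libraries per group are too few to exclude it. Deviations of same-numbered libraries from their group means correlated at 0.118, -0.115 and 0.106, and 3 of 6 libraries correlated best with their own number. With the replicate number as a block, 1792 genes passed (959 up and 833 down), 1697 of them among the 2189, 10 named genes lost their call, Xist and Hpgd gained one (adjusted p 0.0333 and 0.0184), no list that passed did, and immediate early genes turned (adjusted p 0.887).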

Other observations

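The tests of B cells, dendritic cells and macrophages as sources of MHC class II transcripts, and the scan of symbol stems, were chosen after the results were seen, as were the genes named here that the report does not name by its rule. For the count of 2189 genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many and the highest other gave 0. For the count of 11 lists, 5 of the 10 splits gave as many and the highest other gave 15. These 10 splits are too few for a share under 0.05. Each of the 9 others also has libraries of both groups on each side. The difference between the groups then adds to the spread, so a count of 0 genes is not the level expected without an effect. Part of that difference also stays in each of these comparisons, so lists that are shifted between the groups can pass there. Neither a pass in another split nor its count of lists can therefore tell a false call from an effect. Of the 11 lists, 6 (noncanonical NF-kB, NF-kB response, primary granule, antigen presentation, interferon and dendritic genes) had a smaller p in the real split than in each of the 9 others, and 5 did not. The dendritic list did so narrowly (camera adjusted p = 0.0136 against 0.0149). Most of these lists also passed in some of the 9 other splits. The interferon list did in 7, NF-kB response and antigen presentation in 4 each, primary granule and dendritic in 3 each and noncanonical NF-kB in 0.

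Of 392 groups of genes with a shared symbol stem, 5 rose and 2 fell by camera with a preset correlation, and none passed with an estimated correlation (smallest adjusted p 0.993). The latter has little power here, as for the lists. The Il stem, which mixes interleukins, their receptors and the decoy Il18bp, gave 14 of 42 higher and 2 lower (adjusted p = 0.0110). Il2rg, the common gamma chain gene, went from 29.0, 33.4 and 30.3 CPM to 256.7, 287.5 and 271.6 CPM (log2 3.14, edgeR adjusted p = 3.02e-06), and Il12a rose by 1.91 on the log2 scale, while Il31ra (-1.56) and Il4ra (-0.44) fell, the latter not without untreated replicate 1 (adjusted p = 0.0764), untreated replicate 3 (0.0626) or tamoxifen replicate 3 (0.0540). The Tlr stem of Toll-like receptor genes gave 5 of 11 higher (adjusted p = 0.0110), of which Tlr2 and Tlr4, like Il1r1 of the Il stem, also belong to the canonical NF-kB list, which did not pass. The Oas (7 of 7 higher), Ifi (6 of 9) and Gbp stems (7 of 9, 1 lower) share members with the interferon list, and have close copies between which reads can have been split, so their median log2 fold changes of 1.57, 1.57 and 1.69 are uncertain. The Gstm stem of glutathione transferase genes (3 of 5 lower) and the Nt stem, which holds Nt5e (4 of 9 lower), fell by camera (adjusted p = 0.0365 for both).

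Among single genes, St6gal1, a sialyltransferase gene, rose from 1.49, 1.74 and 3.71 CPM to 53.7, 75.6 and 88.2 CPM (log2 4.94, edgeR adjusted p = 0.000103), and St6galnac2 (4.74) and St6galnac3 (4.25) rose from low levels, St6galnac3 not with limma voom (adjusted p = 0.0743), nor without untreated replicate 1 (0.0551), untreated replicate 2 (0.0569) or tamoxifen replicate 3 (0.05003). No group of sialyltransferase genes was tested. Hpgd, the gene of a prostaglandin-degrading enzyme, was at 943.6, 954.7 and 981.0 CPM in the untreated libraries and at 466, 69.5 and 74.9 CPM with tamoxifen, which did not pass (log2 -2.24, edgeR adjusted p = 0.0592) but did without tamoxifen replicate 1 (-3.73, adjusted p = 4.43e-07), with limma voom (-2.84, 0.0148) and with no filter (-2.25, 0.0281).

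MHC class II transcripts (Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita) summed to 26.2, 20.6 and 34.3 CPM untreated and 1461, 1206 and 1913 CPM with tamoxifen, and cells of other types in the sort are a candidate source. The B cell genes Cd79a and Ms4a1 together gained 0.0390% of the CPM that Cd74 gained. This argues against B cells only by a limit set after the results were seen, as the share that B cells would bring was not measured. C1q-expressing macrophages as the main source would keep the ratio of MHC class II to C1q alike, yet it differed 7.91-fold between the tamoxifen libraries. The ratio does not bear on monocytes or macrophages with little C1q, which stay open. The dendritic cell genes Zbtb46, Xcr1, Clec9a, Siglech and Cd209a gained 0.197% of the gain of Cd74. The share such cells would bring was not measured either, so dendritic cells stay open, as do the sort gates, which are not given in the sources used here. An effect of NIK, of tamoxifen or of Cre in the leukaemia cells also stays open and was not tested.

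The macrophage genes C1qa, C1qb, C1qc, Mrc1 and Fcgr1 stood higher in tamoxifen replicate 1 than in the mean of replicates 2 and 3 (median log2 difference 2.59), and macrophages in that library are a candidate explanation for this difference. A second list of 17 tissue macrophage genes, written after the C1q genes were seen and before its own values were, had 13 tested members, 12 of which stood more than 1 log2 unit higher in that replicate (median 1.97), among them Siglec1 (13.5 CPM against 1.39 and 2.61) and Itgad (51.1 CPM against 4.36 and 7.88). None of the 13 was on a list fixed before, but 10 had a mean above 1 CPM in the untreated libraries, among them Hpgd, so not all of the signal need come from macrophages. Without tamoxifen replicate 1 the 5 genes were higher by 2.51 to 4.03 on the log2 scale and passed (adjusted p 0.0116 to 0.0268), against 4.17 to 5.18 with it, so that library alone does not account for the rise, and macrophages in the other tamoxifen libraries, NIK, tamoxifen and Cre stay open for the rest. With all 6 libraries the 5 genes did not pass with limma voom (adjusted p 0.0618 to 0.145, log2 3.98 to 6.17), and in edgeR C1qa, C1qb, C1qc and Fcgr1 did not without untreated replicate 1 (0.0530 to 0.0691) or 2 (0.0525 to 0.0829), C1qa and Fcgr1 not without untreated replicate 3 (0.0743 and 0.0624), and Fcgr1 not without tamoxifen replicate 3 (0.0506), with log2 fold changes of 3.66 to 5.02 for the C1q genes.

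Genes that rose lay next to each other more often than by chance: 228 adjacent pairs both rose, against 97.5 by permutation (p = 1e-04, the smallest that 10000 permutations give), and 121 pairs both fell, against 81.1 (p = 1e-04). Without pairs that share a symbol stem the ratio to chance was 2.04, and without overlapping gene models too it was 1.97, which argues against either as the whole cause. Neighbours can also vary together between libraries of 1 group. As many genes as rose, taken as those highest above their group mean in a single library, gave a median ratio of 1.39 over the 6 libraries (1.06 to 1.45). These genes were ranked without a test, unlike the genes that rose or fell. Noise may therefore lower their ratio, and the comparison cannot decide whether such variation accounts for the pairs. The ratio of 1.53 for pairs that fell lay close to the highest of these. Whether NIK, tamoxifen or Cre accounts for such pairs was not tested. Examples are Trim29 and Thy1 (log2 8.38 and 6.72), Ryr3 and Fmn1 (4.45 and 3.81), and the run of St6galnac2, BC018473 and St6galnac1 (4.74, 4.56 and 7.73) next to Cygb, which had no count in the untreated libraries.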
